A study of Mus musculus with 27 samples.

How the data were processed

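The 27 samples were 3 library types (gene expression, antibody tags and B cell receptor) from 3 pools of each of 3 mice, and each pool held 2 of 6 tissues. Per the labels, mice were perfused, tissues were dissociated and enriched for CD45-positive cells, and cells were stained with tags against CD4, CD8a, CD19, Ly6G and NK1.1 and with 1 of 2 hashtag antibodies before 10x Genomics 5′ V(D)J capture (v1.1). The deposited matrices hold UMI counts of 32285 genes and 7 antibody tags per cell barcode, and the deposited receptor tables hold counts of UMIs per assembled contig. Per the submitters' processing notes both were made with Cell Ranger 5.0.1, and the builds named are GRCm38 and mm10. Per the file headers no value had been normalized, and the receptor tables were filtered to cells and to productive contigs. Columns of per-sample values left out: 0.

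All 3 pools of a mouse share 1 barcode list with 1 suffix, in the matrix and in the receptor table. A cell's mouse and hashtag are known and its pool is not. Cells of different pools with the same barcode would stand as 1 cell in these files. Such merged cells could be neither counted nor told from doublets, and they would add to the cells with markers of both gates, to those with both hashtags and to transcripts of other classes within a gate. No tissue was inferred from a cell's genes. The comparisons planned between mELT and the other tissues could therefore not be run, and those made here, between hashtags and between receptor classes, were chosen once this layout was known, with the tests, gene lists and naming rule that had been fixed before. The analysis keeps the mouse as the replicate, so n = 3.

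Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Barcodes under 200 genes numbered 54, 600 and 399 in mice 1, 2 and 3, and those over 10% mitochondrial 116, 1129 and 1262. A cell was given a hashtag where it held at least 10 hashtag counts, 80% or more of them from 1 hashtag. This assigned 10072, 6937 and 14771 cells to hashtag 1, assigned 10118, 11025 and 11586 to hashtag 2, and left 10673, 6023 and 2772 unassigned. HTODemux (Seurat 5.3.0, positive quantile 0.99), which had been planned as the first rule, called both hashtags in 17.7, 39.8 and 12.0% of cells and was used as the alternative. Cells that both rules assigned, 17930, 10578 and 24616, got the same hashtag in 100% of cases. Both rules read the same 2 counts, so this was nearly bound to hold. They differ in which cells they assign: HTODemux gave hashtag 1 to 11939, 9925 and 13798 cells and hashtag 2 to 9654, 4248 and 11383.

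A cell with 3 or more UMIs of the B marker list and fewer than 3 of the T marker list was put in the B gate, and the reverse in the T gate. These gates are ranges and not types: 517 B gate and 1589 T gate cells held exactly 3 UMIs of their own list. Cells with 3 or more of both, 22.3, 12.1 and 10.9% of cells, were removed as doublets or merged cells. Scrublet in scanpy 1.11.5, with 8% expected doublets, called 0 cells in mice 1 and 2 and so had not worked there. Its threshold in mouse 3, 0.277, was applied to all mice before clustering, and elsewhere as an alternative. T gate cells were called CD4 or CD8 where 1 surface tag exceeded the other by a ratio of 2, and 2335 CD4 cells lay within 25% of it. CD8 cells also had to hold at least 1 UMI of the CD8 marker genes, while CD4 cells had no such rule. Median surface CD4 was 328 counts in the T gate and 33 in the B gate, and median surface CD19 was 27 and 74. Mixed cells and cells above that threshold aside, 70026 cells were clustered with scanpy (10000 UMIs per cell, 2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2 at resolution 0.3) into 12 clusters. Clusters were named from marker lists where at least 3 markers were detected and no other class led. The male and female labels fit the sex-linked genes: Xist had 23, 31615 and 43057 UMIs and Ddx3y 4316, 1 and 0.

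Counts were summed per mouse and group, with at least 20 cells in a sum, and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood) in R 4.3.3 at a Benjamini-Hochberg adjusted p under 0.05. Sums held between 264054 and 15810476 UMIs. The named genes are those with the largest changes per direction, 8 between hashtags and 3 between receptor classes, among genes that passed with at least 50 CPM on the higher side and the same sign in every mouse. Passed over were receptor segments, Gm and Rik genes, mitochondrial, ribosomal and sex-linked genes and markers of other classes, which are given as a group. Up to 4 members are named per list, and Il10, Ebi3, Il12a, Foxp3, Ifng and Il17a whatever their value. Further genes were named after their values were seen: Pdcd1, Ccr6, C1qa, Apoe and Gzma in CD4 T cells, Gfap, C1qa and Lipc in B cells, and S100a9 and Siglech between heavy chains. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1, correlation preset to 0.01, then estimated) and fry. Where a list is named, its median and its test have the same sign, except the T marker list in B cells between hashtags (median 0.07, direction down, not called). In simulated data 100 genes were changed by each fold, drawn from those with over 20 expected counts. All genes had the same dispersion and the sums of a mouse were drawn independently. Lower genes and the real spread and pairing were thus not covered. The edgeR step was run on these data. It recovered 46, 39, 50, 20 and 72% of 2-fold and 100, 96, 95, 80 and 99% of 4-fold changes in the comparisons of B cells between hashtags, of CD4 T cells, of B cells between heavy chains, of switched cells and of V beta, with 6, 6, 8, 6 and 4 false calls.

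Groups shared their mice, so mouse numbers pair the sums by design. The deviations of paired sums correlated at 0.293, -0.0323 and -0.0837 for B cells between hashtags, 0.454, 0.0446 and -0.0155 for CD4 T cells, 0.322, 0.202 and 0.246 between heavy chains, 0.192, 0.0666 and 0.0846 for switched cells and 0.567, 0.431 and 0.303 for V beta. The fit without the block is the one reported, as planned, and the blocked values are given where they change a call.

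Heavy and light chains were taken from cells with 1 contig of that kind. Of 46774 contigs, 19195 were heavy, 24904 kappa and 2675 lambda, and 14451 of 31455 B gate cells (45.9%) had 1 heavy chain. The files do not say which chain is the knock-in, and the most frequent CDR3 nucleotide sequence was taken as it. Light-chain groups share V, J and CDR3 bases, and groups were compared after thinning to equal cell numbers (100 draws), except where the report gives unthinned shares. Shares and log2 levels were compared by a two-sided exact permutation test (smallest p 0.1) and paired within mice (smallest p 0.25). V beta use came from Trbv gene counts, with Trbv16 taken as the V beta of 2D2, which the files do not state, with cells thinned to 1500 UMIs for shares of cells. Myelin transcripts were summed over the oligodendrocyte marker list. A count of 0 allows up to 3, and intervals are 95%, both for counting error only.

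The alternatives were HTODemux, relative log expression, DESeq2 1.42.0, no filter on low counts, the mouse as a block, each mouse left out, at most 5% mitochondrial, removal by scrublet score, mixed cells kept, classes by cluster or surface tag, without cluster 3 or 5, knock-in cells alone, matching for UMIs, at least 50 cells per sum, at least 5 UMIs per contig, thresholds of 50 or 200 heavy-chain UMIs, without cells of 100 or more, paired chains only, all barcodes with a contig, groups by CDR3 amino acids, and the myelin list without Cnp. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.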

Results

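CD45-enriched cells of 3 Thx2D2 mice were profiled by droplet sequencing of messenger RNA, of B cell receptor transcripts and of antibody tags on the cell surface. These mice carry a knock-in immunoglobulin heavy chain and a T cell receptor transgene, 2D2, both specific for myelin oligodendrocyte glycoprotein, and they develop experimental autoimmune encephalomyelitis without immunization. The mice, 1 male and 2 females, were untreated and were taken 25 ± 6 days after disease onset. From each mouse, meningeal ectopic lymphoid tissue (mELT), cerebrospinal fluid, blood, spleen, and lumbar and inguinal lymph nodes were pooled 2 at a time under 2 hashtag antibodies. Hashtag 1 marked cerebrospinal fluid, lumbar node and spleen, and hashtag 2 marked mELT, inguinal node and blood. The 3 pools of a mouse share 1 barcode list, so each cell could be traced to its mouse and its hashtag but not to its tissue. The comparisons are therefore between hashtags, each a mixture of 3 tissues, and between cells that differ in their antigen receptor, with n = 3 mice throughout. Mice 1, 2 and 3 gave 80693854, 58528413 and 90520893 gene UMIs in 31029, 25668 and 30756 barcodes, with medians of 1697, 1613 and 2475 UMIs per barcode. After filtering, 30863, 23985 and 29129 cells remained, of which 31455 fell in the B cell gate and 32509 in the T cell gate. The CD4 class held 24738 T cells and the CD8 class 591.

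The first comparison asked which cell populations the hashtag 2 tissues, mELT among them, held in other proportions than the hashtag 1 tissues. T-like cluster 2, led by the naive T cell genes Lef1, Tcf7 and Dapl1, made up 15.96 ± 9.45% of hashtag 2 cells and 39.1 ± 6.67% of hashtag 1 cells (SD, n = 3 mice), and was lower in hashtag 2 in 3 of 3 mice. T-like cluster 4, led by Izumo1r, Tnfrsf4, Tnfrsf9, Ctla4 and Lag3, genes of activated and regulatory T cells, made up 9.31 ± 3.66% and 3.06 ± 1.39%. Macrophage-like cluster 8, led by the complement genes C1qa and C1qb, made up 4.95 ± 1.51% and 1.99 ± 0.903%. Cluster 5 made up 12.7 ± 10.7% and 0.470 ± 0.217%. It stayed unnamed because the myelin genes Mbp, Mobp and Plp1 stood among its leading genes although 96.6% of its cells lay in the B cell gate. Egr1, Fos, Fosb and Cd83 were among its leading genes too. The oligodendrocyte markers had been kept out of the variable genes used for clustering. Clusters 4, 5 and 8 were higher in hashtag 2 in 3 of 3 mice.

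NK-like cluster 6 was lower in hashtag 2 in 3 of 3 mice (2.94 ± 0.99% against 5.63 ± 0.770%), and so was T-like cluster 9, led by the gamma delta receptor gene Trdc (1.06 ± 0.311% against 2.22 ± 0.810%). B-like cluster 1 made up 27.7 ± 14.8% of hashtag 2 cells and 37.8 ± 3.33% of hashtag 1 cells, a difference within the spread between mice. Cells outside both gates made up 10.3 ± 2.21% of hashtag 2 cells and 5.56 ± 1.65% of hashtag 1 cells. Each of these shares except that of cluster 1 gave a two-sided exact permutation p of 0.1, the smallest that 3 mice against 3 allow, and 0.229 after Benjamini-Hochberg adjustment over the 16 shares compared. The p of cluster 1 was 0.4 (exact permutation, adjusted 0.582). Cluster 3, 7015 cells of low RNA content with a median of 855 UMIs, held 51.1% of the hashtag 2 cells of mouse 2 and at most 3.52% of any other mouse and hashtag, and it was not named. That share rests on the hashtag rule, since HTODemux hashtags gave 7.95%. All shares are of clustered cells, so cluster 3 lowered every other hashtag 2 share of mouse 2. In that mouse cluster 6 was 2.79% against 4.88% and cluster 9 was 0.699% against 1.28%. Shares without cluster 3 were not computed, so these 2 differences in mouse 2 cannot be told from its effect. With HTODemux hashtags clusters 6 and 9 were also lower in hashtag 2 in 3 of 3 mice. Under HTODemux the exact permutation p was 0.2 for cluster 8, 0.3 for cluster 9 and 0.5 for cells outside both gates. Without mouse 1 the difference of cluster 5 was 6.14 points in place of 12.2. The leading genes of cluster 4 were among those that differed within CD4 T cells, so its share and that comparison are not independent, and no fit without cluster 4 was run.

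**Figure D1:**
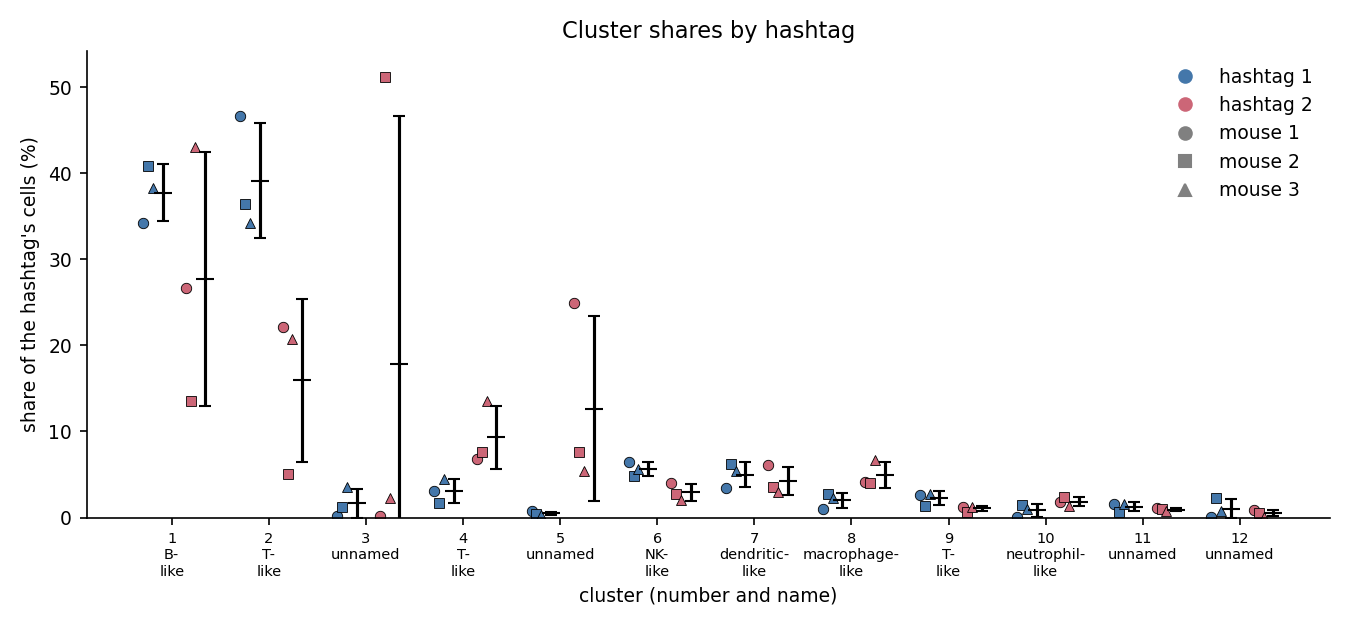
Share of each hashtag's cells (%, y axis) in 12 clusters (x axis), with 1 point per mouse and the mean ± SD beside the points. Clusters 4, 5 and 8 lie higher in hashtag 2 in 3 of 3 mice. Cluster 3 held 51.1% of the hashtag 2 cells of mouse 2 (7.95% with HTODemux hashtags) and at most 3.52% of any other mouse and hashtag shown.

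CD4 T cells of the hashtag 2 tissues were asked for a state of their own, since 2D2 T cells recognize a myelin antigen. Genes of several inhibitory and costimulatory receptors were among those that passed the test. Lag3, which encodes an inhibitory receptor for MHC class II, rose by 3.47 ± 0.38 on the log2 scale (SE, n = 3 mice), from 6.17 to 72.6 CPM, the count scaled to equal library size. Tnfrsf9 rose by 3.39 ± 0.45 and Tnfrsf4 by 2.19 ± 0.28, which encode the costimulatory receptors 4-1BB and OX40. Ctla4 rose by 1.82 ± 0.19, Pdcd1 by 1.98 ± 0.24, the T cell receptor response gene Nr4a1 by 2.13 ± 0.33 and the folate receptor gene Izumo1r by 1.84 ± 0.27. The glycolysis gene Tpi1 rose by 1.80 ± 0.19, Rilpl2 by 1.47 ± 0.21 and the Th17 chemokine receptor gene Ccr6 by 1.61 ± 0.17. Dtx1, an E3 ligase gene of the Notch pathway, fell by 1.50 ± 0.25, from 56.1 to 19.7 CPM. Each of these genes moved the same way in 3 of 3 mice. Foxp3 was 11.1 CPM in hashtag 1 and 30.0 CPM in hashtag 2 cells, a difference of 1.40 ± 0.35 that did not pass the threshold (adjusted p 0.152, edgeR quasi-likelihood with Benjamini-Hochberg adjustment; 0.00436 to 0.991 over its alternatives). Ifng (adjusted p 0.847, edgeR) did not pass either, and Il17a, with 10 and 38 UMIs, was too low to test (ratio of CPM 4.17, 95% counting interval 2.04 to 9.39).

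In that test, edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, 87 of 10951 genes were higher and 3 lower in hashtag 2 CD4 T cells at an adjusted p under 0.05. The adjusted p was 0.00644 for Lag3, 0.0155 for Tnfrsf9, 0.0142 for Tnfrsf4, 0.00541 for Ctla4 and Tpi1, and 0.0383 for Dtx1, and it reached 0.991 for each of them over the alternatives, with T cells taken by surface tags. When the mouse was entered as a block the test called 183 genes, 89 of the 90 among them, and DESeq2 called 249. Without mouse 1 it called 103, without mouse 2 it called 19 and without mouse 3 it called 10. Under HTODemux hashtags it called 163 genes, and without the low-RNA cluster 3 it called 137. With T cells taken by surface tags in place of marker UMIs it called 0, with 241 genes at an unadjusted p under 0.05 (edgeR; no other tool was run on those cells). Transcripts of macrophages and microglia rose too, C1qa by 2.92 ± 0.36 and Apoe by 3.28 ± 0.58, and the NK gene Gzma fell by 1.48 ± 0.25, so part of the difference lay in transcripts of other cell classes.

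**Figure D2:**
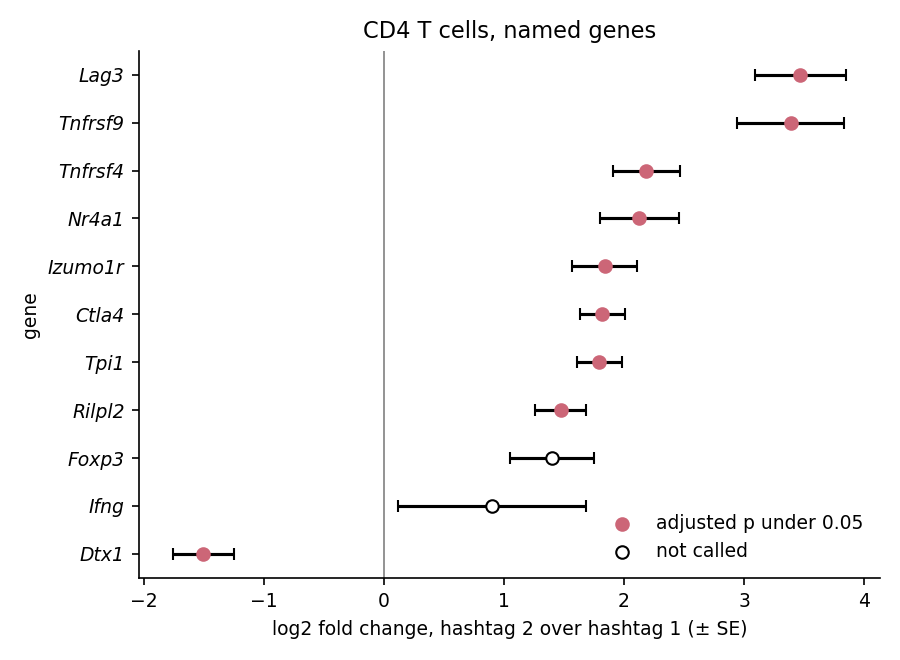
Log2 fold change ± SE (x axis, hashtag 2 over hashtag 1, n = 3 mice) of the named genes in CD4 T cells (y axis). Filled points passed an adjusted p of 0.05 (edgeR quasi-likelihood), from Lag3 at 3.47 to Dtx1 at -1.50, and open points, Foxp3 at 1.40 and Ifng at 0.90, did not.

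Gene lists written before the data were examined were tested in the same CD4 T cell sums with camera at a preset correlation. Of the 11 tested genes of the regulatory T cell list, 7 were higher over all genes tested and 9 when adjusted over the list alone, with a median log2 difference of 1.70. Its largest members were Tnfrsf9, Tnfrsf4, Itgae and Izumo1r. The inhibitory receptor list had 3 of 10 higher, or 7 adjusted over the list alone, with a median of 1.22. The follicular helper list had 2 of 10, or 6 adjusted over the list alone (median 1.34), and the Th17 list 1 of 7, or 6 adjusted over the list alone (median 1.00). The tissue residency list had 1 of 9, or 4 adjusted over the list alone (median 0.79), and the glycolysis list 2 of 13, or 8 adjusted over the list alone (median 0.47). None of the 11 naive T cell genes passed, and their median was -0.34. The Th1 list (median 0.10 over 12 genes) was not called, with an adjusted camera p of 0.692. Camera called 24 of 36 lists, 20 up and 4 down, and with an estimated correlation 0 of the 24 held. The adjusted p was then 0.0520 for the regulatory, inhibitory receptor, follicular helper, residency and glycolysis lists, 0.0550 for Th17 and 0.0725 for the naive list. Fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes, called 12. Beside these, the macrophage markers had 4 of 7 higher (median 2.40, adjusted p with the estimated correlation 0.0520) and the NK markers 1 of 8 lower (median -1.10, also 0.0520). At the preset correlation camera also called the neutrophil, monocyte and dendritic markers and the neutrophil maturation and antigen presentation lists up, and the erythroid markers down.

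B cells of hashtag 2 and hashtag 1 were compared for the same reason. Genes of oligodendrocytes, astrocytes and macrophages were among those that passed the test. Mbp, which encodes myelin basic protein, rose by 4.60 ± 0.40 on the log2 scale (SE, n = 3 mice), from 31.1 to 751 CPM. Mobp rose by 6.43 ± 0.66 and Plp1 by 3.71 ± 0.44, both genes of oligodendrocytes, and the astrocyte gene Gfap rose by 5.42 ± 0.43. Plekhb1 rose by 6.65 ± 0.62, from 0.713 to 50.9 CPM. The lysosomal protease gene Ctsd rose by 1.55 ± 0.19, Samsn1, an adaptor gene of B cell signalling, by 0.92 ± 0.12, and Sfn by 0.84 ± 0.12. The complement gene C1qa rose by 3.14 ± 0.44. Each of these was higher in 3 of 3 mice. Of the genes that fell the test found 1, the germinal centre gene Lipc, by 1.93 ± 0.29, while DESeq2 found 109. The cytokine subunit genes Ebi3 (-0.11 ± 0.18, adjusted p 0.920, edgeR) and Il12a (-0.16 ± 0.17, adjusted p 0.850, edgeR) did not pass, and Il10, with 13 and 10 UMIs, was too low to test (ratio of CPM 0.517, 95% counting interval 0.203 to 1.28).

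Of 11408 genes, 32 were higher and 1 lower in hashtag 2 B cells (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The adjusted p was 0.00370 for Mbp, 0.00498 for Plekhb1, 0.0261 for Ctsd, 0.0322 for Samsn1 and 0.0374 for Sfn. Over the alternatives it reached 0.266 for Plekhb1, 0.760 for Ctsd, 0.989 for Samsn1 and 0.788 for Sfn, and their lowest log2 differences were 4.93, 0.29, 0.53 and 0.60. A block for the mouse raised the count to 93 genes, 72 higher and 21 lower, the 33 among them. DESeq2 called 245, 136 higher and 109 lower. Without mouse 1 the test called 204 genes, 105 higher and 99 lower, and without mouse 2 or mouse 3 it called 14 each. The near absence of lower genes thus depended on the method and on mouse 1. Without cluster 5 it called 10 genes, with B cells taken by surface tags 1, and with B cells taken as cluster 1 it called 0, with 720 at an unadjusted p under 0.05 (edgeR; no other tool was run on those cells). The oligodendrocyte list had 3 of 5 genes higher (4 adjusted over the list alone, median 3.71), the microglia list 2 of 5 (4 adjusted over the list alone, median 2.54) and the macrophage list 2 of 8 (4 adjusted over the list alone, median 1.63). The marginal zone list had 0 of 9 lower over all genes and 7 when adjusted over the list alone, with a median of -1.36 and Asb2, S1pr3, Myof and Dtx1 as its largest members. The germinal centre list had 1 of 12 lower (5 adjusted over the list alone, median -1.13), the proliferation list 0 of 18 (14 adjusted over the list alone, median -0.95) and the NK markers 0 of 8 (8 adjusted over the list alone, median -1.72). The antigen presentation list (median 0.30 over 15 genes) and the interferon list (median -0.41 over 19) had 0 genes either way. Camera called 18 of 38 lists, 10 up and 8 down. The neutrophil markers and the neutrophil maturation list were among those up, and the plasmacytoid markers among those down. With an estimated correlation 0 of the 18 held. The adjusted p was then 0.0577 for the oligodendrocyte and microglia lists, 0.203 for macrophages, 0.0985 for NK, 0.285 for the marginal zone and proliferation lists, 0.472 for the germinal centre list, and 0.528 for antigen presentation and interferon. Fry called 3, the oligodendrocyte, microglia and NK lists.

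The B cell receptor data were asked how often the knock-in heavy chain was found. It was much rarer in class-switched B cells, and in cells with much heavy-chain RNA, than in other B cells. The most frequent heavy-chain CDR3, of IGHV1-9 and IGHJ2 and 13 amino acids long, was taken as the knock-in chain. It was found in 12596 of 14451 B cells with 1 heavy chain (87.2%). IgM or IgD cells carried it in 88.0 ± 0.446% (SD, n = 3 mice), and switched cells in 14.2 ± 5.69%, or 23 of 174 cells (95% Clopper-Pearson interval 8.57 to 19.2%, for counting error only). By isotype it was in 86.5% of 11297 IgM and 94.1% of 2761 IgD cells, in 29.5% of 44 IgA cells, and in 2 of 20 IgG1, 3 of 46 IgG2b, 2 of 34 IgG2c and 3 of 30 IgG3 cells.

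Cells outside the T cell gate with 100 or more heavy-chain UMIs, a level typical of antibody-secreting cells, carried the knock-in chain in 5.95 ± 2.59%, or 7 of 101 cells (Clopper-Pearson interval 2.83 to 13.8%), against 87.6 ± 0.757% under 100 UMIs. Of them 49.4 ± 4.17% were switched, against 0.986 ± 0.335%. Each of these differences had the same direction in 3 of 3 mice, a two-sided exact permutation p of 0.1, the smallest possible, and 0.15 after Benjamini-Hochberg adjustment over the 18 receptor comparisons. The knock-in share was 85.9 ± 3.88% in hashtag 2 and 88.3 ± 4.54% in hashtag 1 (exact permutation p 0.5, adjusted 0.6), and the switched share was 1.07 ± 0.585% and 1.31 ± 1.18% (0.9, adjusted 0.953). Both differences were within the spread between mice. Near matches of the knock-in CDR3, with 1 or 2 differing bases, made up 5.21 ± 9.02% of switched and 0.131 ± 0.0923% of IgM or IgD chains of its length, but the 5 switched ones all came from mouse 3 (exact permutation p 1).

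**Figure D3:**
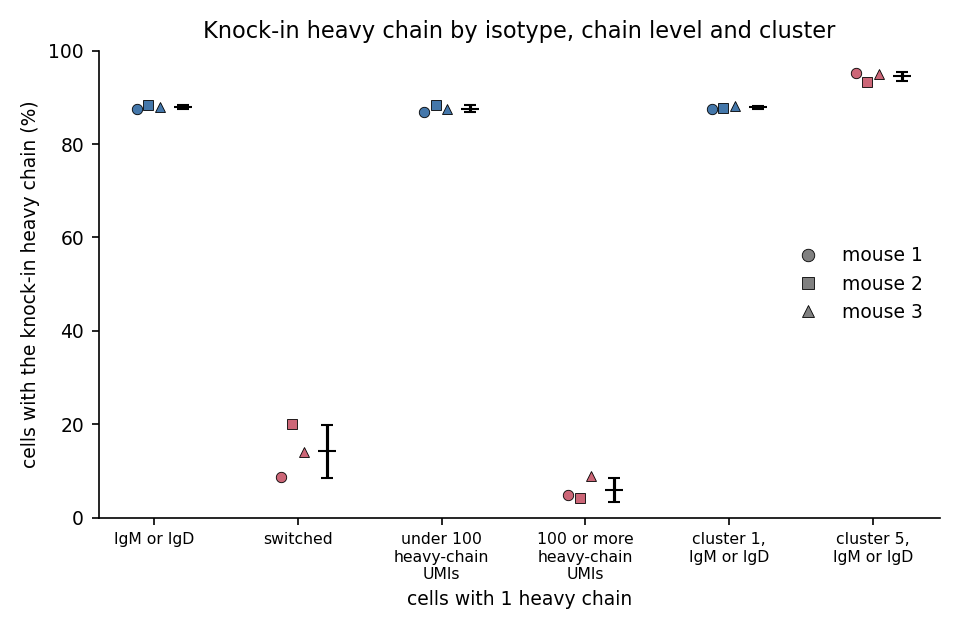
Share of cells with the knock-in heavy chain (%, y axis) by isotype, heavy-chain UMIs and cluster (x axis), with 1 point per mouse and the mean ± SD. Switched cells lie at 14.2% and cells with 100 or more heavy-chain UMIs at 5.95%, against 88.0% of IgM or IgD cells and 94.5% of IgM or IgD cells in cluster 5.

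Among unswitched cells, those with another heavy chain were compared with those that carried the knock-in chain. Cells with another heavy chain held more transcript of the antibody-secreting program. Jchain, whose product joins IgM into polymers, rose by 4.99 ± 0.93 on the log2 scale (SE, n = 3 mice), from 124 to 3941 CPM. Derl3, a gene of protein quality control in the endoplasmic reticulum, rose by 3.13 ± 0.19 and the transcription elongation gene Eaf2 by 3.10 ± 0.33. The genes of naive B cells Fcer2a, Satb1 and Ccr6 fell by 1.07 ± 0.12, 1.02 ± 0.16 and 1.00 ± 0.17. Ebi3 (0.26 ± 0.20, adjusted p 0.658, edgeR) and Il12a (-0.69 ± 0.25, adjusted p 0.260, edgeR) did not pass, and Il10 was too low to test, with 3 and 12 UMIs (ratio of CPM 23.0, 95% counting interval 6.22 to 127).

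Between these cells, 542, 442 and 705 with another chain and 3823, 3392 and 5154 with the knock-in chain in mice 1, 2 and 3, 188 of 9950 genes were higher and 31 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The adjusted p was 0.0373 for Jchain, 0.000404 for Derl3, 0.00319 for Eaf2, 0.00480 for Fcer2a, 0.0201 for Satb1 and 0.0249 for Ccr6. With the mouse as a block 379 genes were called, and DESeq2 called 373. Without mouse 1 the count was 247, without mouse 2 it was 67 and without mouse 3 it was 58. With the cells of both kinds matched for UMIs it was 82. Cells with 100 or more heavy-chain UMIs, 10, 9 and 21 in mice 1, 2 and 3, held 8.42, 9.12 and 9.87% of the UMIs of cells with another chain, and at most 0.321% of those of knock-in cells. Without them 171 genes were called, 154 of the 219 among them, and Fcer2a, Satb1 and Ccr6 still passed. Jchain (2.23, adjusted p 0.272), Derl3 (1.32, 0.123) and Eaf2 (2.04, 0.107) no longer did (edgeR; over all alternatives 7.82e-06 to 0.561, 1.65e-35 to 0.123 and 2.92e-16 to 0.107). The lists were not tested without these cells. All 8 plasma cell markers were higher (median 2.64), as were 10 of 13 genes of the plasma program list (12 adjusted over the list alone, median 1.58, largest Jchain, Tnfrsf17, Sdc1 and Derl3). Of the memory and age-associated list 4 of 11 were higher (5 adjusted over the list alone, median 0.95, largest Zbtb32, Cd80, Nid1 and Cxcr3), and of the transitional and B1 list 2 of 7 (4 adjusted over the list alone, median 1.17). Of the naive follicular list 2 of 10 were lower (6 adjusted over the list alone, median -0.54). Camera called 12 of 31 lists. With an estimated correlation 2 held, the plasma markers (adjusted p 0.0281) and the plasma program (0.0381), while the memory list was at 0.0563, the B1 list at 0.0607 and the naive follicular list at 0.2004. Under a block for the mouse, camera also called the B cell marker, macrophage, marginal zone, antigen presentation and oxidative phosphorylation lists, at adjusted p from 0.0217 to 0.0350. The neutrophil gene S100a9 fell by 3.30 ± 0.58 and the plasmacytoid gene Siglech by 3.32 ± 0.52, transcripts of other classes.

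Switched B cells were set against IgM or IgD cells in the same way. Most genes of the plasma program, proliferation and germinal centre lists were higher in them, but of these lists proliferation alone kept its call with an estimated correlation, and 2 genes passed once cells were matched for UMIs. Slpi, a protease inhibitor gene, rose by 6.50 ± 0.68 on the log2 scale (SE, n = 3 mice), from 31.1 to 2810 CPM. Jchain rose by 4.51 ± 0.35 and the germinal centre GTPase gene Nuggc by 4.87 ± 0.63. Rflnb, Cnn3 and Zfp318, the last of which is needed to make IgD transcripts, fell by 2.91 ± 0.44, 2.84 ± 0.30 and 2.69 ± 0.27. Il12a was counted 627 times in IgM or IgD cells and 3 times in switched cells, a ratio of CPM of 0.159 with a 95% counting interval of 0.0326 to 0.465, and its test passed (adjusted p 0.0362, edgeR) but not with the mouse as a block (adjusted p 0.0644, edgeR; 0.00588 to 0.194 over its alternatives). Ebi3 did not pass (0.13 ± 0.31, adjusted p 0.885, edgeR), and Il10, with 15 and 2 UMIs, was too low to test (ratio of CPM 4.42, 95% counting interval 0.490 to 19.0).

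Of 9839 genes, 662 were higher and 445 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), with 58, 30 and 86 switched cells in mice 1, 2 and 3. The adjusted p was 0.00139 for Slpi and Cnn3, 0.000471 for Jchain, 0.00296 for Nuggc, 0.00548 for Rflnb and 0.00128 for Zfp318. DESeq2 called 1573 genes. Without mouse 1 the test called 889, without mouse 2 it called 185 and without mouse 3 it called 128. Switched cells were deeper, with medians of 3513, 4525.5 and 3770.5 UMIs against 1119, 2433 and 2391. With cells matched for UMIs 2 genes were called, but matching left 58, 30 and 86 IgM or IgD cells. In these, cells with 100 or more heavy-chain UMIs held 12.4, 8.02 and 13.5% of the UMIs, against 1.44, 1.42 and 1.67% before matching. The drop therefore cannot be put down to depth alone. Cells with 100 or more heavy-chain UMIs held 31.6, 50.2 and 47.5% of the switched UMIs, and without them 446 genes were called. Of the proliferation list 16 of 18 were higher (18 adjusted over the list alone, median 2.54) and of the naive follicular list 8 of 10 lower (10 adjusted over the list alone, median -1.64). The plasma program had 12 of 13 higher (12 adjusted over the list alone, median 3.11), the germinal centre list 8 of 12 (11 adjusted over the list alone, median 3.27), and the interferon list 7 of 18 lower (8 adjusted over the list alone, median -0.88). The antigen presentation list had 8 of 15 lower and 1 higher (12 and 1 adjusted over the list alone, median -0.64). Camera called 19 of 30 lists, of which proliferation (adjusted p 0.0148) and naive follicular (0.0211) held with an estimated correlation. The others named here were then at 0.146, 0.220, 0.188 and 0.402. With the mouse as a block the tissue residency list was called too (adjusted p 0.0308). Some transcripts of other cell classes were fewer in switched cells, with 3 of 3 tested neutrophil markers lower (S100a8 by 4.47 ± 0.82) and 0 of 4 oligodendrocyte markers (3 adjusted over the list alone, median -2.37), both too few for camera. Of the B cell markers 6 of 8 were lower (8 adjusted over the list alone, median -0.98, adjusted p with the estimated correlation 0.148).

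Light chains were compared because the knock-in heavy chain leaves them as the variable part of the receptor. Knock-in B cells of the 3 mice shared more of them than other cells did. IGKV17-127 was used by 15.2 ± 0.468% of knock-in cells and 1.30 ± 0.316% of cells with another heavy chain (SD, n = 3 mice), and IGLV1 by 9.19 ± 0.460% of knock-in cells. Groups of identical V, J and CDR3 bases that held 2 or more cells took 85.7 ± 0.326% of knock-in and 51.4 ± 2.27% of other cells, each thinned to 420 cells. Groups found in all 3 mice, at 420 cells per mouse, held 75.9% of knock-in and 30.4% of other cells (means of 100 draws, not tested). Without thinning they held 94.4% of 12418 and 35.7% of 1673 cells, shares that also reflect the numbers of cells. The IGKV17-127 and group differences had an exact permutation p of 0.1 (adjusted 0.15) and the same direction in 3 of 3 mice. Lambda use was lower with another heavy chain in 3 of 3 mice (8.13 ± 1.52% against 9.72 ± 0.749%, paired difference -1.59 ± 0.989 points), without passing a test (exact permutation p 0.3, adjusted 0.386; paired p 0.25, the smallest that 3 pairs allow). Of hashtag 2 knock-in cells, thinned to 966, 94.0 ± 2.07% belonged to a light-chain group found with hashtag 1 in the same mouse and 91.9 ± 0.498% to one found in the other mice. These are shares of cells and not of groups. They were higher in the same mouse in 3 of 3 (paired difference 2.09 ± 2.44 points, exact permutation p 0.2, adjusted 0.277, paired p 0.25).

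T cell receptor V segments were read from the 5′ ends of transcripts, to ask which T cells used another V beta than Trbv16, which was taken as that of 2D2. Nearly all V beta transcripts were of Trbv16, whose counts do not tell a transgenic from an endogenous segment. Trbv16 gave 99.3% of the V beta UMIs of CD4 T cells, and Trbv13-1 followed with 0.233%. CD4 T cells with at least 1 Foxp3 UMI, 683 of 24738, are called Foxp3-positive and the others Foxp3-negative, although a cell without a UMI may express the gene, and 0.294 ± 0.173% of B cells held a Foxp3 UMI against 2.75 ± 0.604% of CD4 T cells (SD, n = 3 mice). Foxp3-positive CD4 T cells had 2.02 ± 1.20% of their V beta UMIs from other segments, Foxp3-negative ones 0.591 ± 0.0994% and CD8 T cells 6.53 ± 1.15% (SD, n = 3 mice). Of the V beta UMIs of B cells, a background, 0.831 ± 0.613% came from other segments, within that spread of Foxp3-negative cells. Both classes were above Foxp3-negative cells in 3 of 3 mice, with an exact permutation p of 0.1 (adjusted 0.15).

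Thinned to 1500 UMIs per cell, 18.5 ± 5.63% of Foxp3-positive, 9.25 ± 0.191% of Foxp3-negative and 31.6 ± 4.69% of CD8 T cells held another V beta, after 117, 8075 and 103 shallower cells were left out. Unthinned, the shares were 28.1 ± 7.11, 12.8 ± 2.88 and 36.5 ± 8.43%. B cells, which should hold none, had 0.659 ± 0.451% thinned and 1.32 ± 0.975% unthinned, at a median of 1879 UMIs per cell against 3105, 2200 and 2773. That background is of other segments only, and the B gate, which admits fewer than 3 UMIs of the T marker list, may keep it low. Trbv16 was missing in just 43.9 ± 17.3% of B cells (unthinned), so a Trbv16 UMI does not show that a cell expresses it. In mouse 1 the thinned shares of Foxp3-positive and Foxp3-negative cells were 11.97 and 9.14%, the smallest gap of the 3 mice. The share of other V beta UMIs was 0.723 ± 0.393% in hashtag 2 and 0.617 ± 0.3504% in hashtag 1 CD4 T cells, within the spread between mice (exact permutation p 0.6, adjusted 0.675).

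CD4 T cells with another V beta were compared with as many cells of Trbv16 alone, matched for UMIs. The 10 genes called, all higher, were V beta segments such as Trbv13-1, Trbv13-2, Trbv31 and Trbv19, by which the cells had been chosen (9590 genes, 889, 895 and 1522 cells per side in mice 1, 2 and 3, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 225 genes, and DESeq2 called 18. Without mouse 2 or mouse 3 the test called 2 genes, and without mouse 1 it called 14. With the mouse as a block it called 106, 51 higher and 55 lower. Foxp3 was 33.7 CPM against 17.6 (0.97 ± 0.34), which passed only with the mouse as a block (adjusted p 0.00842, edgeR; up to 1 over its other alternatives). Ifng did not pass (1.097 ± 0.789), and Il17a, with 28 UMIs against 5, was too low to test (ratio of CPM 5.57, 95% counting interval 2.12 to 18.5). The Th17 list had 0 of 6 genes higher over all genes and 5 when adjusted over the list alone (median 0.63, largest Ccr6, Rorc, Rora and Maf). The NK markers had 0 of 8 lower and 7 adjusted over the list alone (median -0.80). Camera called 14 of 34 lists, 6 up and 8 down. Those up were the Th17, Th1, regulatory, follicular helper, homing and tissue residency lists. Those down were the NK, monocyte, macrophage, dendritic, plasmacytoid and erythroid markers and the antigen presentation and germinal centre lists. With an estimated correlation the NK markers alone held (adjusted p 0.0337), while Th17 was at 0.161. The block added the memory, B1 and naive T cell lists, at adjusted p of 0.0401, 0.00204 and 0.00972.

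**Figure D4:**
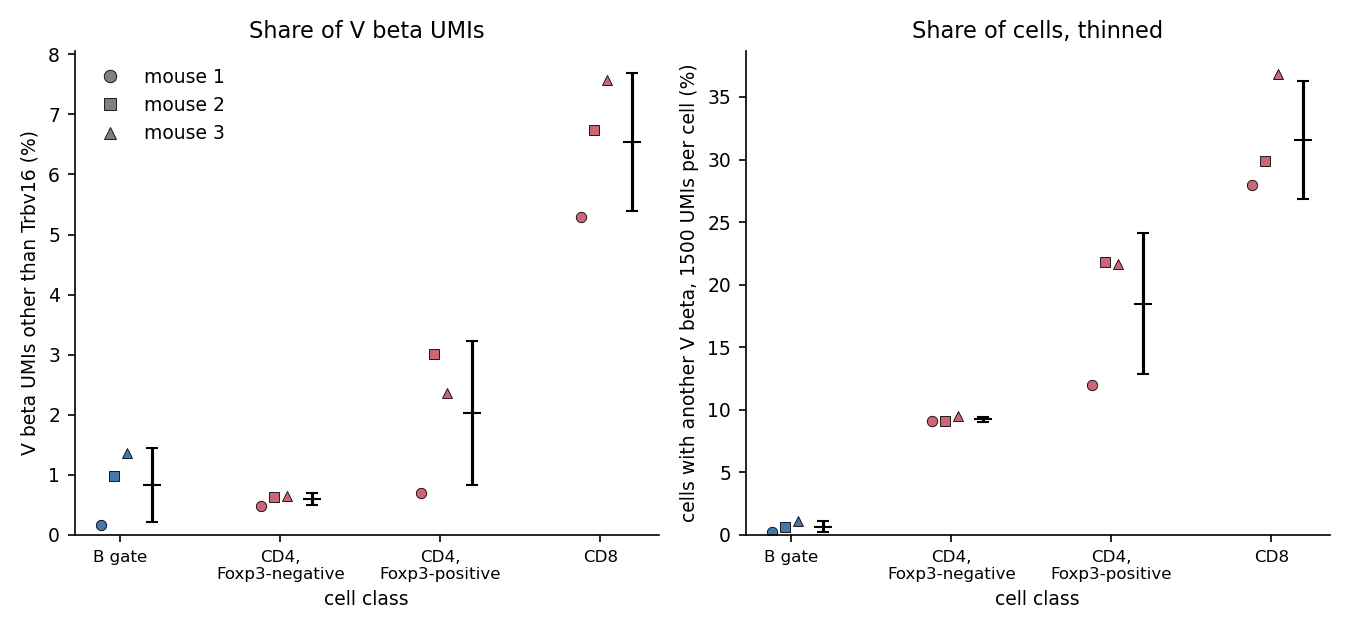
Left, V beta UMIs other than Trbv16 (% of V beta UMIs, y axis); right, cells with another V beta after thinning to 1500 UMIs (%, y axis), by cell class (x axis), with 1 point per mouse and the mean ± SD. CD8 T cells lie highest, at 6.53 and 31.6%, and B cells, a background that their gate may keep low, at 0.831 and 0.659%.

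Myelin transcripts were followed in B cells because their knock-in receptor binds a myelin protein. They were most abundant in hashtag 2 B cells that carried the knock-in chain. Summed over 6 oligodendrocyte genes, they made up 1114 ± 420 CPM of hashtag 2 B cells (SD, n = 3 mice), 254 ± 38.8 CPM of hashtag 1 B cells, 260 ± 45.5 CPM of hashtag 2 T cells and 222 ± 26.4 CPM of hashtag 1 T cells. Hashtag 2 B cells were 2.06 ± 0.42 above hashtag 1 B cells and 2.03 ± 0.70 above hashtag 2 T cells on the log2 scale (SD). Among IgM or IgD cells of hashtag 2, those with the knock-in chain held 1225 ± 557 CPM and those with another chain 403 ± 83.9 CPM, a log2 difference of -1.50 ± 0.76. Within cluster 5 the values were 2417 ± 541 and 1072 ± 270 CPM, a log2 difference of -1.17 ± 0.21. In hashtag 1 they were 259 ± 41.9 and 251 ± 47.1 CPM. IgM or IgD cells of cluster 5 carried the knock-in chain in 94.5 ± 0.987%, and those of cluster 1 in 87.8 ± 0.378%. Myelin genes led cluster 5, so its knock-in share and the contrast within it are not independent of the myelin levels. In hashtag 2 cells outside cluster 5 the knock-in cells held 657 ± 206 CPM and the others 332 ± 68.9 CPM. Each difference except those within hashtag 1 and outside cluster 5, which were not tested, held in 3 of 3 mice, with an exact permutation p of 0.1 (adjusted 0.15). The depth was 836 cells with another chain in hashtag 2 and 82 in cluster 5.

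Mbp carried most of these myelin differences. Without Mbp, the other 5 genes made up 349 ± 53.4 CPM of hashtag 2 and 223 ± 41.3 CPM of hashtag 1 B cells. By heavy chain they made up 363 ± 60.1 CPM of knock-in and 255 ± 38.1 CPM of other cells in hashtag 2, a log2 difference of -0.50 ± 0.28, and 538 ± 69.7 and 342 ± 55.0 CPM in cluster 5, a log2 difference of -0.63 ± 0.05 (SD, n = 3 mice). Cnp, which is also expressed outside oligodendrocytes, worked the other way. Without Cnp hashtag 2 B cells were 4.51 above hashtag 1 B cells on the log2 scale, and the differences between heavy chains were -2.41 in hashtag 2 and -1.41 in cluster 5.

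**Figure D5:**
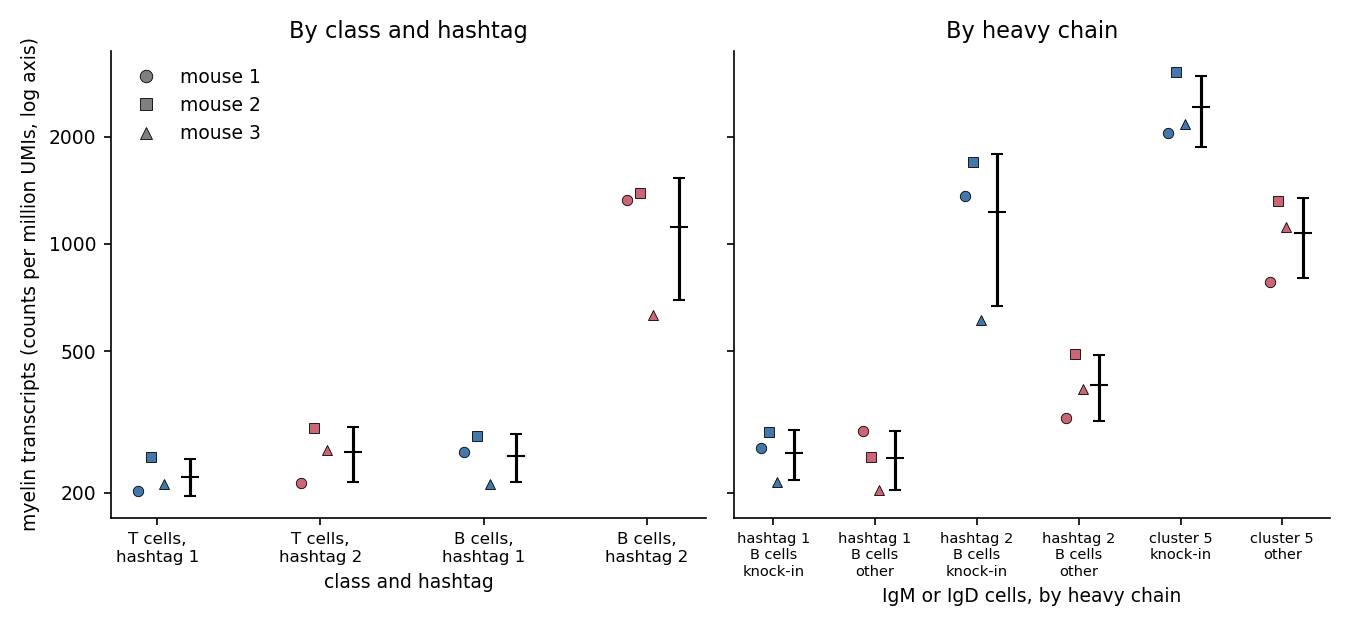
Myelin transcripts (CPM, log y axis) by class and hashtag on the left and by heavy chain on the right (x axes), with 1 point per mouse and the mean ± SD. Knock-in cells lie above cells with another chain in hashtag 2 (1225 against 403 CPM) and cluster 5 (2417 against 1072 CPM), and beside them in hashtag 1 (259 against 251 CPM).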

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

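All tests in this part were chosen after the results were seen, except that of myelin binding by the receptor, whose prediction was written before its result. Heavy chains also appeared outside the cells compared: 144 T gate cells had 1 (0.443% of 32509, with a median of 4 heavy-chain UMIs against 5 in the B gate), as did 4204 cells with markers of both gates (32.4% of 12966, against 45.9% of the B gate). A further 158 barcodes with a heavy chain were not among the cells kept after filtering on genes and mitochondrial UMIs. How many of those barcodes were in the matrix before filtering was not counted. They are listed because each count is above the 3 that a count of 0 allows, a limit that leaves out doublets and free RNA and so excludes neither. Of the cells with both markers 86.3 ± 2.39% carried the knock-in chain (SD, n = 3 mice), and of the barcodes outside the kept cells 70.9%. No biological explanation of these was tested.

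Myelin transcripts were fewer in hashtag 2 B cells with another heavy chain than in knock-in cells. Free myelin RNA reaching all hashtag 2 cells alike would give each cell as many myelin UMIs, but cells with another chain had fewer (log2 difference in UMIs per cell -1.29 ± 0.54, SD, n = 3 mice), which argues against that form alone. Hashtag 2 cells came from 3 pools with libraries of their own, so this does not bear on free RNA within a pool. Free RNA through where each kind of cell had been cannot be told apart from other explanations: macrophage and microglia transcripts in cluster 5 were 0.68 ± 0.20 higher with another chain, against the direction of myelin, but each pool has macrophage RNA of its own and the pool of a cell is unknown. Binding of myelin through the receptor stays open: among 4265 knock-in cells the myelin level, taken without Cnp, depended on 17 light-chain V genes in a partly shared order (mean Spearman rho between mice 0.353, one-sided permutation p 0.0155, 2000 shuffles), and macrophage transcripts did not (rho -0.0245, p 0.621). With Cnp, a test added later, rho was 0.251, under the 95% point of shuffled sets (0.255, p 0.0530), so the result rests on leaving Cnp out, and the order may equally reflect where cells with certain light chains were, so it stays a hypothesis.

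The knock-in chain was rare among cells with 100 or more heavy-chain UMIs. Mutated knock-in chains that no longer match would raise the share to near 87.6% once chains of up to 4 differing bases are counted, but it rose to 12.7 ± 3.28% (SD, n = 3 mice). Class switching alone would leave the share of IgM or IgD chains unchanged, but in the 52 such cells it was 7.47 ± 6.81%, against 88.0% of all IgM or IgD cells. Differences between tissues stay open, and no biological explanation was tested.

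Other V beta segments were more frequent in Foxp3-positive than in Foxp3-negative CD4 T cells. More RNA per cell as the whole cause would remove the gap after thinning, which cut it from 15.3 ± 4.99 to 9.22 ± 5.54 percentage points (SD, n = 3 mice). Depth may thus account for part of it. In mice 2 and 3 a gap of 12.7 and 12.1 points was left, which argues against depth as the whole cause there. In mouse 1 it fell from 9.53 to 2.83 points with 142 Foxp3-positive cells, too few to tell. The thinned gap was not tested. Doublets of T cells would bring Trbv16 along, but Foxp3-positive cells lacked Trbv16 more often, by 6.46 ± 3.25 points. Free RNA would reach B cells too, of which 1.32% held another V beta. The B gate, however, admits only cells with fewer than 3 UMIs of the T marker list. Cells with more T cell RNA were thus left out, so this background may be too low and does not exclude free RNA. Differences between tissues stay open, and no biological explanation was tested.

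For the counts of called genes, 1 of 10 splits of the 6 sums, the real one, gave as many genes in each comparison. The real and highest other counts were 33 and 0 for B cells between hashtags, 90 and 0 for CD4 T cells, 219 and 0 between heavy chains, 1107 and 0 for switched cells and 10 and 1 for V beta. Among the 4 splits that part every mouse, the highest other count was 0 in each (edgeR). With 10 splits the share is never under 0.1.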

How the results depend on the processing

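All alternatives reported here were chosen after the layout of the data was known, though the same kinds had been listed before for tissues. Those listed for mELT against the other tissues, for lumbar against inguinal node and for neutrophils were not run, because the pool of a cell is unknown. Of 314 values of counts and shares 268 stayed within the spread between mice, or within 1.5 times for counts, and 46 moved. For shares and receptor values, the block leaves the value as it is, and leaving out a mouse cannot shift a mean by its SD. These values were bound to count as within the spread, so they say nothing about stability. The 214 named genes gave 465 results over the 5 comparisons, with 6886 values under alternatives: 6298 kept their call or lack of it, 302 lost it, 282 gained it and 4 changed sign with a call on either side. The 39 lists gave 169 results with 1453 values: 1229 kept their call or lack of it, 148 lost it, 71 gained it and 5 changed sign with a call on either side. Among the values counted as kept, 158 of genes and 89 of lists changed sign with no call on either side. The cause was not tested unless given.

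Genes called in B cells between hashtags were 33. They were 245 by DESeq2, 343 with no filter, 93 with the replicate block, 54 with mixed cells kept (29 shared), 1 by surface tags, 10 without cluster 5 and 0 with the class by cluster (edgeR, 720 at an unadjusted p under 0.05; no other tool was run), and 14 to 204 with a mouse left out (14 without mouse 2 or 3, 204 without mouse 1). CD4 T cells gave 90 genes. They were 249 by DESeq2, 304 with no filter, 183 with the block, 163 by HTODemux (86 shared), 137 without cluster 3 (85 shared), 0 by surface tags (edgeR, 241 at an unadjusted p under 0.05; no other tool was run), and 10 to 103 with a mouse left out (19 without mouse 2, 10 without mouse 3).

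Between heavy chains 219 genes were called. They were 373 by DESeq2, 522 with no filter, 379 with the block, 54 by surface tags, 82 matched for UMIs (76 shared), where fewer cells entered, and 58 to 247 with a mouse left out (67 without mouse 2, 58 without mouse 3). Switched cells gave 1107 genes. They were 514 with the class by cluster, 2 matched for UMIs and 446 without cells of 100 or more heavy-chain UMIs, both with fewer cells, and 128 to 889 with a mouse left out (185 without mouse 2, 128 without mouse 3). For V beta 10 genes were called. They were 18 by DESeq2, 23 with no filter, 106 with the block, and 2 to 14 with a mouse left out (2 without mouse 2 or 3). The block changed the list calls, Foxp3 and Il12a as the report gives them. Of the other list members named there, Asb2 passed in B cells between hashtags (adjusted p 0.0228, edgeR; 0.000861 to 0.471 over its alternatives), and Ccr6, Rora and Maf for V beta (0.00158, 0.0298 and 0.00505, each up to 1 over its alternatives). Among lists it changed those of the report, with plasma program in CD4 T cells losing its call (adjusted p 0.117) and homing (0.0477) and, in B cells between hashtags, dissociation stress gaining theirs. It changed no other call of a count, share or list.

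Among switched cells Entpd1 changed sign to -1.74 without cells of 100 or more heavy-chain UMIs, Tpi1 to -0.00700 matched for UMIs, and Hsp90aa1 to -0.22 with the class by cluster and -0.34 matched for UMIs. The T marker list in B cells changed sign by surface tags, where its signed log10 p was 7.70. With a mouse left out, 4 lists changed sign on that scale: immunoglobulin constant (-0.984 to 2.497) and interferon (-9.83 to 0.0361) in B cells between hashtags, and neutrophil markers (-0.767 to 2.41) and neutrophil maturation (-3.19 to 4.90) for V beta. They rested on mouse 3, or mouse 1 for interferon.

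The knock-in share at 100 or more less that under 100 heavy-chain UMIs, -81.6 points, was -78.5 at 5 or more UMIs per contig and -73.5 from 50 heavy-chain UMIs, where the switched share differed by 36.0 points. At 5 or more UMIs per contig the knock-in share of cluster 5 exceeded cluster 1 by 10.6, IGKV17-127 differed by -14.7 and cluster 5 myelin by -1.46. Groups of 2 or more cells differed by -29.7 by CDR3 amino acids. Without Cnp, a gene also expressed outside oligodendrocytes, myelin differed by 4.51 between hashtags in B cells, by -2.41 between heavy chains in hashtag 2 and by -1.41 in cluster 5. Under HTODemux the share of cluster 4 differed by 9.17 points. Within the spread between mice, the difference of cluster 3 fell from 16.2 to 1.66 points, the exact permutation p of clusters 8 and 9 and of cells outside both gates rose from 0.1 to 0.2, 0.3 and 0.5, and the B gate became higher (10.1 points) and the T gate lower (-10.4 points) in 3 of 3 mice (p 0.1 each). With a mouse left out, no difference could leave the spread. The difference moved by over 1.5 times or changed sign for cluster 1 (-17.4 to -1.41 points), cluster 3 (-0.607 to 25.0) and cluster 5 (6.14 to 15.7), for the knock-in share (-6.56 to 1.86), switched share (-0.874 to 0.727) and V beta (-0.231 to 0.454) between hashtags, and for near matches (-0.0914 to 7.69), lambda use (-1.90 to -1.02) and cells with shared light-chain groups (0.738 to 3.11). It did so too for clusters 7, 10, 11 and 12 and the B, T and mixed gates. Depth limits the switched cells (174) and those with 100 or more heavy-chain UMIs (101), and Il10 and Il17a could not be tested.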

Other observations

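The values here belong to no planned comparison and were chosen after the data were seen. Of 1855 heavy chains other than the knock-in, 190 (10.2%) shared its last 27 CDR3 bases while using 42 different V genes, with 184 different CDR3 sequences, of which 4 were switched. The next most frequent end occurred in 14 chains (0.755%). IGHV1-69 (17 chains) and IGHV9-3 (16) were the V genes most often joined to it. The 5 largest light-chain groups held 20.8 ± 0.764% of knock-in cells (SD, n = 3 mice). The most frequent other CDR3 was found in 8 cells. In hashtag 2 there were 5.47 ± 0.874 Plp1 UMIs per 100 Mbp UMIs in B cells and 3.98 ± 1.19 in T cells, and 10.04 ± 1.07 Mobp UMIs in B cells and 3.63 ± 2.11 in T cells (SD, n = 3 mice).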
